A study of Homo sapiens with 4 samples.

How the data were processed

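Small RNA was sequenced from MCF7 cells, an established line of estrogen receptor positive breast cancer cells. There were 4 libraries with 1 library per group. The groups were normoxic MCF7, hypoxic MCF7, MCF7 overexpressing HIF-1 alpha (HIF1A, the oxygen-regulated subunit of the transcription factor HIF-1), and breast tumor initiating cells (BTIC) derived from MCF7. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with the NEBNext kit for small RNA. The labels repeat a treatment of 1% hypoxia for 18 h on every sample, the normoxic sample included, so they do not say whether the HIF-1 alpha and BTIC cultures were also kept at low oxygen.

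The authors deposited 1 table of raw read counts, whole numbers per annotated transcript that are not normalised. Per the submitters' processing notes, Bowtie and HOMER were used with the human genome build hg19, with no versions given. Adapter trimming and the handling of reads that map to several places are not given in the sources used here. Positions are those of the deposited table on hg19. The reference at hand was of another build and was not used for positions. The column names of the table are not the sample titles. Normal, Hypoxia and Hif1a each matched the words of 1 sample. The column named Sorted was matched to the BTIC sample, the 1 sample described as a subpopulation derived from another culture, although the labels do not use the word. All BTIC values below rest on this match.

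The table held 1696 rows, of which 1625 were miRNA hairpins, 55 were miRNA host transcripts, 14 were protein-coding and 2 were of other kinds. A host transcript row repeats the reads of the hairpins inside it, so that MIR210HG holds the reads of MIR210. Library totals are sums over all rows and include these repeats. Some hairpins that give the same mature miRNA from several places had nearly equal counts and others did not (MIR16-1 and MIR16-2 had 174 and 414 normoxic reads), and their values were not assigned to a single locus. There were 53 such hairpin rows of 24 mature names among those with enough reads.

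Rows with at least 50 reads over the 4 libraries were compared, which left 238 rows, 214 of them hairpins. Counts were scaled with edgeR's TMM (edgeR 4.0.16 in R 4.3.3). A ratio between a pair of libraries was computed from scaled counts with a prior count of 0.5. Its interval is the exact (Clopper-Pearson) 95% interval of the ratio of 2 Poisson counts. A row was put as higher or lower when its ratio was at least 2-fold and the interval excluded 1. Reads carry no molecular identifiers, so intervals and floors cover counting error only. With 1 library per group there is no replicate check, no p-value was computed, and every difference is between libraries, not between conditions. Where a library had 0 reads, the fold is a lower bound against a floor of 3 counts in that library. No fold is given where both libraries were at or under 3 counts, and such rows were left out of list medians.

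For 18 lists of miRNAs, fixed before the data were examined, the median log2 ratio of the hairpin rows was placed among 10000 random lists of the same size, matched on mean abundance in 10 bins. The percentile describes these libraries and is no test. Lists with fewer than 3 compared rows have no percentile. Some miRNAs are members of several lists, so the lists are not separate sets. The lists were hypoxia-induced, hypoxia-repressed, let-7, miR-200, miR-183/96/182, miR-17-92 and its paralogs, embryonic stem cell, luminal breast, basal and mesenchymal breast, fibroblast and smooth muscle, p53-responsive, blood, muscle, neural, liver and endothelial miRNAs, and the imprinted cluster of chromosome 14 and the miRNA cluster of chromosome 19.

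The rule for named rows was also fixed before the data were examined. It took, in each of the 3 comparisons against the normoxic library, up to 8 rows with the largest and up to 8 with the smallest ratio among those put as higher or lower, with at least 100 normalised CPM (counts scaled to a common library size) in either library, or at least 20 where fewer than 4 passed. It also took up to 4 most abundant members of each list, miR-210 in every library, and the 5 most abundant rows of each library. Rows named outside this rule are marked as chosen after their values were seen.

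The steps were tested on simulated counts of 1696 rows in which 200 rows were changed 4-fold. Of the changed rows with enough reads, 21 of 23 (91.3%) were recovered for the hypoxic comparison, 23 of 24 (95.8%) for the HIF-1 alpha comparison and 18 of 20 for the BTIC comparison. Of the unchanged rows, 2 of 186, 0 of 185 and 2 of 190 were called. Apart from the changed rows, each simulated library was drawn from the normoxic profile with counting error alone. The simulation therefore checks the steps and gives no error rate for the real libraries, which differed by more than counting error. The alternatives were scaling by the library total, by DESeq2 median of ratios (DESeq2 1.42.0), by the upper quartile and by TMM over hairpin rows, other read minimums (1 and 500), copies of a mature miRNA summed, a prior count of 5 and a 4-fold threshold. Chosen after seeing the data were a count over hairpin rows alone and scaling by the total without miR-21. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.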

Results

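Small RNA reads were counted in 1 library each of normoxic MCF7, hypoxic MCF7, MCF7 overexpressing HIF-1 alpha, and MCF7-derived BTIC, in a series made to find miRNAs that respond to hypoxia. The library totals were 1107428 reads (normoxic), 1312311 (hypoxic), 1237587 (HIF-1 alpha) and 676322 (BTIC). There were no replicates, so no difference below was set against replicate error, and each interval in parentheses is the exact 95% counting interval of the ratio.

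MIR21, a miRNA abundant in many cancers (chromosome 17, 57918627 to 57918698), made up most reads of the MCF7 libraries. Its share was 82.5% (exact binomial 95% interval 82.4 to 82.6) in the normoxic library, 83.5% (83.4 to 83.5) in the hypoxic library and 79.4% (79.3 to 79.5) in the HIF-1 alpha library. In the BTIC library the share was 41.4% (41.3 to 41.6). Reads outside miR-21, on which the other values rest, numbered 193968, 217132, 255163 and 396036 in the same order, with the repeats in host rows included. Over hairpin reads alone the miR-21 share was 85.6%, 86.5%, 82.9% and 50.8%. After miR-21 the most abundant rows of the normoxic library were MIRLET7F2, MIRLET7F1, MIRLET7I and MIR200B, at 0.840%, 0.824%, 0.757% and 0.627% of reads. The hypoxic and HIF-1 alpha libraries held the same 3 let-7 rows and MIR27B in these places, with MIR27B at 0.539% and 0.703%. In the BTIC library these places were taken by MIR20A at 2.80%, MIR92A1 at 2.79%, MIR92A2 at 2.65% and MIR148A at 2.14%. Host transcript rows held 3.61%, 3.47%, 4.28% and 18.4% of reads. Across compared rows the log CPM of the normoxic library correlated with that of the hypoxic library at Pearson's r = 0.991, the HIF-1 alpha library at 0.963 and the BTIC library at 0.713 (rows are not independent replicates), and no pair of libraries agreed within sampling noise.

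The comparison of hypoxic with normoxic MCF7 asks which miRNAs differ after low oxygen. MIR210, the best known miRNA target of HIF-1 (chromosome 11, 568089 to 568198, inside the host transcript MIR210HG), had 53 reads (60.2 CPM) in the normoxic and 248 reads (282 CPM) in the hypoxic library, 4.65-fold higher (3.47 to 6.43). MIR503 (X chromosome, 133680358 to 133680428, inside MIR503HG) was 2.57-fold higher (1.64 to 4.21), with 27 and 70 reads. MIR450A2, in the same X chromosome cluster (133674538 to 133674637), was 2.17-fold higher (1.37 to 3.59), with 27 and 59 reads. MIR326 had 7 and 19 reads (2.60-fold, 1.09 to 7.65) and MIR320B2 had 7 and 18 reads (2.47-fold, 1.03 to 7.29). Of the 238 rows, 8 were higher and 0 lower. The 8 rows were these 5 hairpins, the host rows MIR210HG and MIR503HG with the same reads, and MIR3158-1, named after its values were seen, with 4 and 15 reads.

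All 22 compared rows of the hypoxia-induced list, which includes miR-210, had ratios above 1 in the hypoxic library (14 under total scaling), with 1 of them (MIR210) higher by the 2-fold rule and 21 neither. The list's median log2 ratio was 0.34, at percentile 99.9 of matched random lists, against a median of 0.17 over all compared rows. Among its abundant members MIR27A was at 1.62-fold (1.53 to 1.71), MIR26A1 at 1.35-fold (1.29 to 1.43) and MIR27B at 1.19-fold (1.15 to 1.23). The p53-responsive list (6 rows) had a median of 0.62, at percentile 99.0, with none past the 2-fold rule. Its members included MIR34A, a direct p53 target, at 1.63-fold (1.23 to 2.18) and MIR192 at 1.48-fold (1.296 to 1.68), whereas MIR107 was at 1.02-fold (0.804 to 1.3) and MIR143, with 15 and 10 reads, at -0.56. The median was the midpoint of MIR192 and its chromosome 11 neighbour MIR194-2, so these rows are not independent. MIR192 and MIR107 are also members of the hypoxia-induced list. The miR-17-92 list (12 rows, oncogenic miRNAs of chromosome 13 and their paralogs) had a median of -0.09, at percentile 1.68, also with none past the rule under TMM. The medians of the other lists lay inside the central 95% of random lists. They were 0.13 for the hypoxia-repressed list (7 rows), 0.19 for let-7 (12), 0.02 for miR-200 (5), 0.11 for the MIR183, MIR96 and MIR182 cluster (3), 0.33 for luminal (5), 0.22 for basal and mesenchymal (8) and 0.13 for neural miRNAs (5), each with 0 higher and 0 lower, and all but the luminal median were below 0 under total scaling.

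These hypoxic ratios depended on the scaling. TMM left the median of all rows at 0.17, while scaling by the total, by the median of ratios and by the upper quartile put it at -0.08, -0.01 and -0.05. Under each of these 3, 5 rows were higher and 2 lower, with MIR326, MIR320B2 and MIR450A2 no longer higher and MIR106A and MIR1273H, named after their values were seen, lower.

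**Figure D1:**
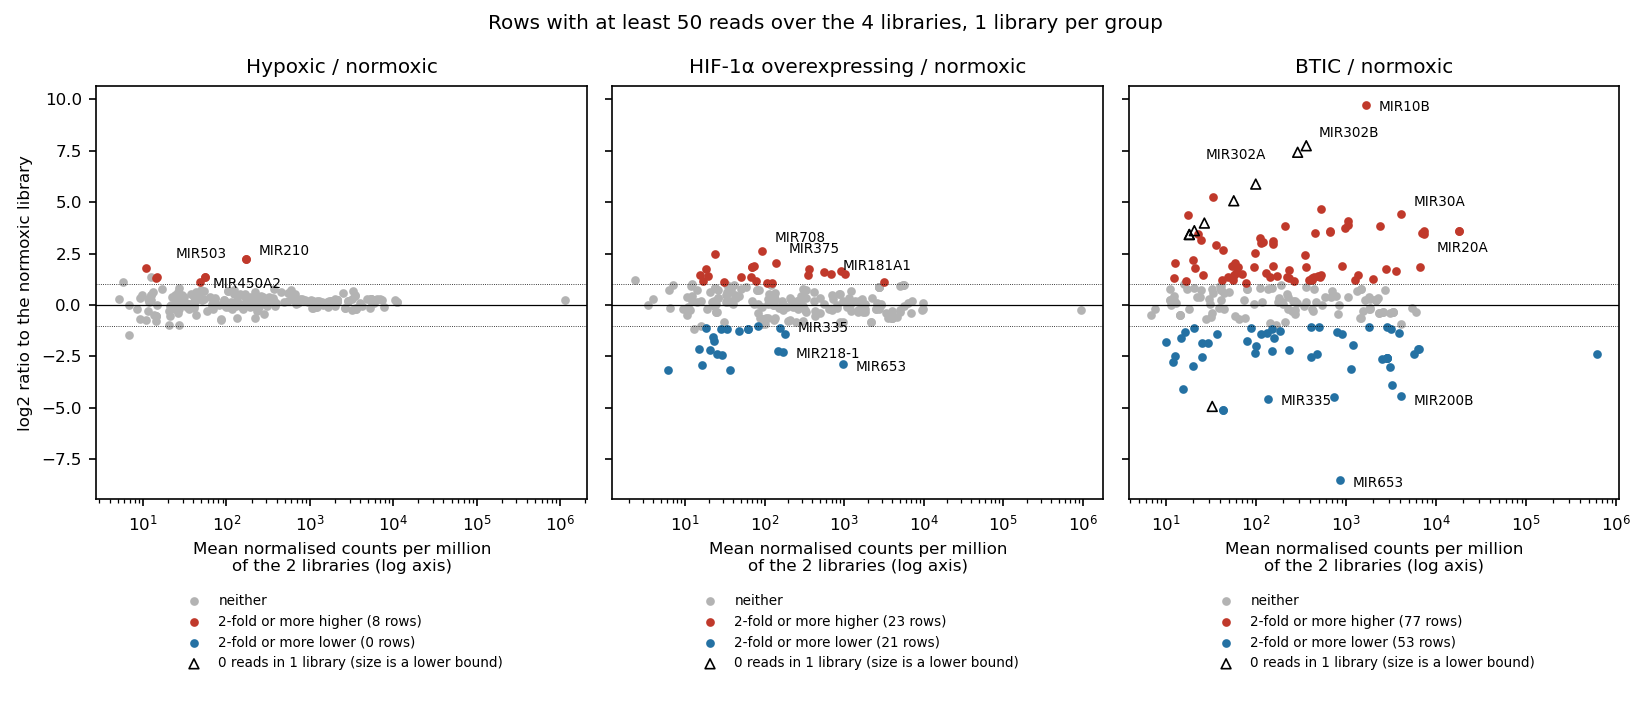
Log2 ratio of each compared row to the normoxic library (y axis) against the mean normalised CPM of both libraries (x axis, log scale), for the hypoxic, HIF-1 alpha and BTIC libraries. Red rows were at least 2-fold higher and blue rows at least 2-fold lower with a counting interval that excluded 1, and open triangles are rows with 0 reads in 1 library, drawn at their lower bound. Counts of higher and lower rows were 8 and 0, 23 and 21, and 77 and 53 under TMM scaling.

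The comparison of HIF-1 alpha overexpressing with normoxic MCF7 asks which miRNAs differ when HIF-1 alpha is supplied in excess. MIR708 (chromosome 11, 79113066 to 79113153) was 6.24-fold higher (4.08 to 10.4), with 22 and 180 reads. MIR375, a miRNA of endocrine and luminal epithelial cells (chromosome 2, 219866367 to 219866430), was 4.08-fold higher (3.02 to 5.73). From the X chromosome cluster, MIR450A2 was 3.75-fold (2.5 to 5.99) and MIR503, with its host row MIR503HG, 3.55-fold higher (2.36 to 5.68). MIR181B2 was 3.32-fold (2.78 to 4.0) and MIR181A2 3.01-fold higher (2.62 to 3.49), and their host row MIR181A2HG 3.13-fold. MIR210 had 115 reads (102 CPM), 1.68-fold of the normoxic library (1.21 to 2.38), short of the 2-fold rule.

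Among the lower rows, MIR653 (chromosome 7, 93112072 to 93112167) went from 1521 normoxic reads to 264, 7.39-fold lower (6.49 to 8.47). MIR218-1 was 4.88-fold (3.72 to 6.55) and MIR218-2 4.69-fold lower (3.52 to 6.42), copies that give the same mature miRNA and cannot be told apart. MIR335 was 2.69-fold (2.14 to 3.41), MIR615 2.20-fold (1.73 to 2.82) and MIR455 2.04-fold lower (1.47 to 2.86). In all, 23 rows were higher and 21 lower (20 and 19 among hairpins). The split was 39 and 14 under total scaling, where MIR615 and MIR455 were not lower, 17 and 28 under the median of ratios, and 18 and 26 under the upper quartile.

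Of the hypoxia-induced list's 22 rows, 4 were higher in the HIF-1 alpha library, 1 lower and 17 neither, with a median of 0.15 at percentile 90.9 (-0.03 under the median of ratios). The 4 higher rows were the copies of miR-181a and miR-181b and the lower row was MIR195 (not lower under total scaling), named after their values were seen. The luminal list (5 rows) had a median of 0.63, at percentile 98.7, with MIR375 higher, MIR149 at 1.74-fold (1.47 to 2.07), MIR425 at 1.55-fold (1.35 to 1.80) and MIR203A at a log2 ratio of -0.36. The basal and mesenchymal list (9 rows) had a median of -0.63, at percentile 1.075, with 1 row lower and 0 higher (0 and 1 under total scaling, 2 and 0 under the median of ratios and the upper quartile). The lower row was MIR205, with 75 and 42 reads, named after its values were seen. The abundant member MIR22 went the other way, at 1.81-fold (1.71 to 1.92), and over rows with at least 500 reads the list's median was 0.02. The miR-17-92 list (12 rows) had a median of -0.59, at percentile 0.18, with 1 row lower and 1 higher (0 and 1 under total scaling, 4 and 0 under the median of ratios, 2 and 0 under the upper quartile). The higher row was MIR25, at 2.13-fold (2.02 to 2.25) but 1.89-fold under the median of ratios, and MIR20A stood at -0.83. The neural list (5 rows) had a median of -0.66, at percentile 0.35, with no row past the rule (1 lower under the median of ratios and the upper quartile). It rested on the copies MIR9-1, MIR9-2 and MIR9-3 (the last named after its values were seen), at -0.67, -0.66 and -0.92. With copies of a mature miRNA summed, the list of neural miRNAs fell under the 3-row minimum and the basal list was inside the central 95%. Other medians were inside it at -0.31 (hypoxia-repressed), -0.19 (let-7, 0.01 under total scaling), 0.08 (miR-200, -0.09 under the median of ratios), -0.35 (MIR183, MIR96 and MIR182) and 0.67 (p53-responsive, with 1 of 6 rows higher, 3 under total scaling and 0 under the median of ratios and the upper quartile), with 0 higher and 0 lower in the first 4 under TMM. The hypoxia-repressed list had 1 row higher under total scaling and 1 lower under the median of ratios.

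BTIC are cells labelled as able to initiate tumors, and their comparison with normoxic MCF7 asks which miRNAs differ in them. Their counts are those of the column named Sorted, matched to this sample by reasoning alone. The 4 miR-302 hairpins, miRNAs of pluripotent cells (chromosome 4, 113569160 to 113569713), had 0 reads in the normoxic library. In the BTIC library they had 1016 (MIR302B), 815 (MIR302A), 159 (MIR302D) and 75 (MIR302C) reads, at least 214.2-fold, 172-fold, 33.5-fold and 15.8-fold higher. MIR367, another pluripotent cell miRNA named after its values were seen, had 0 normoxic reads and 1 BTIC read. MIR10B, which lies in the HOXD gene cluster (chromosome 2, 177015031 to 177015140), had 3 and 4712 reads, an 852-fold ratio (340 to 4819). MIR452 (X chromosome, 151128100 to 151128184) had 0 and 279 reads, at least 58.8-fold higher. MIR18A was 25.4-fold (18.4 to 37.1), MIR30A 21.3-fold (19.1 to 23.9) and MIR9-1 17.1-fold higher (14.1 to 21.1).

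On the lower side, MIR653 had 1521 normoxic and 6 BTIC reads, 370-fold lower (184 to 1094). MIR335 was 23.8-fold lower (14.6 to 44.6). The epithelial miRNAs MIR429, MIR200B and MIR200A (chromosome 1, 1102484 to 1104467) were 22.6-fold (18.3 to 28.5), 21.8-fold (19.9 to 23.95) and 14.7-fold lower (13.5 to 16.1), and MIR200C was 8.11-fold lower (7.57 to 8.71). MIR203A, a miRNA of differentiated epithelia, was 8.56-fold (7.62 to 9.65) and MIR99A 6.14-fold lower (5.72 to 6.59). MIR210 was at 1.68-fold (1.23 to 2.37), short of the rule. There were 77 rows higher and 53 lower (74 and 46 among hairpins). Rows that met the read minimum through BTIC reads alone, such as the miR-302 rows and MIR10B, were bound to be higher. They were not counted separately. Total scaling, under which the lower miR-21 share raises all other rows, shifted the median of all rows from 0.26 to 1.63 and gave 163 higher and 21 lower, with MIR210 among the higher. The upper quartile put it at -0.30 and gave 52 higher and 65 lower. Of the 130 rows put as higher or lower under TMM, 12 had a ratio on the other side of 1 under total scaling, and none was put on the other side.

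All 5 miR-200 rows, which keep epithelial cells from mesenchymal change, were lower in the BTIC library, with a median of -3.88 at percentile 0.03. Their reads summed to 18731 in the normoxic and 2197 in the BTIC library, 13.5-fold lower after scaling (12.9 to 14.1). Under total scaling 4 of the 5 were lower. Of the 12 let-7 rows, miRNAs of differentiated cells, 8 were lower and 4 neither, with a median of -1.71 at percentile 0.06. MIRLET7I was 5.26-fold (5.03 to 5.50) and MIRLET7F2 4.45-fold lower (4.28 to 4.63), whereas the 3 copies of let-7a, named after their values were seen, stood between -0.28 and -0.19. Under total scaling 3 let-7 rows were lower and 3 higher. The miR-17-92 list had 9 of 12 rows higher (12 under total scaling) and 0 lower, with a median of 3.36 at percentile 100. MIR20A was 11.95-fold (11.2 to 12.8), MIR92A1 11.05-fold (10.4 to 11.8) and MIR17 14.1-fold higher (12.6 to 16), while MIR25 of the chromosome 7 paralog stood at 0.74.

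The embryonic stem cell list held the 4 miR-302 rows, with a median of 8.83, or 6.25 with each row at its lower bound, at percentile 100. These rows met the read minimum through BTIC reads alone, so a high placement was fixed in advance and the percentile carries no weight. Other members of the list fell under the minimum and stayed near 0. MIR367 had 1 BTIC read and MIR372 and MIR373 had 0, named after their values were seen. The basal and mesenchymal list split, with 4 of 9 rows higher and 4 lower and a median of 0.26 at percentile 40.0 (-0.04 under the median of ratios, and 5 higher and 1 lower under total scaling). MIR221 was 11.9-fold (9.71 to 15.02) and MIR222 11.4-fold higher (8.90 to 14.9), while MIR205 had 75 normoxic and 3 BTIC reads. MIR10B, also among the higher rows, met the read minimum through BTIC reads alone. The neural list had 3 of 5 rows higher (5 under total scaling) and a median of 3.76 at percentile 99.7. All 3 were copies of miR-9, and MIR128-1 and MIR128-2 stood at 0.40 and 0.44 (-0.16 and -0.12 under the upper quartile). The clustered MIR183, MIR96 and MIR182 were lower, with a median of -1.39 at percentile 9.3, and none of them under total scaling, where the median was -0.01. Further medians were inside the central 95%, at -0.23 for the hypoxia-induced list (0 higher, 3 lower), 0.29 for hypoxia-repressed (3 higher, 0 lower), -0.97 for luminal (0 higher, 2 lower) and -0.17 for p53-responsive miRNAs (1 higher, 0 lower). Under total scaling the hypoxia-induced, luminal and p53-responsive medians were 1.15, 0.40 and 1.20, and under upper quartile scaling the hypoxia-repressed median was -0.27, so the sign of these 4 is not fixed. Under total scaling 15 of 22 hypoxia-induced rows, 7 of 7 hypoxia-repressed, 2 of 5 luminal and 5 of 6 p53-responsive rows were higher, with 1 luminal row lower. Under the upper quartile 7 hypoxia-induced and 3 luminal rows were lower, and 2 hypoxia-repressed and 0 p53-responsive rows higher.

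Summed reads of fibroblast, blood, muscle and liver miRNAs were low in all libraries. In the normoxic, hypoxic, HIF-1 alpha and BTIC libraries they were 60, 66, 59 and 63 for fibroblast and smooth muscle miRNAs, 11, 8, 31 and 11 for blood, 5, 11, 5 and 19 for muscle, and 0, 0, 2 and 1 for liver. The endothelial marker MIR126 had 665, 779, 729 and 2456 reads, 2.33-fold higher in BTIC (2.14 to 2.55) under TMM and not past the 2-fold rule under the median of ratios (1.90-fold) or the upper quartile (1.58-fold). The imprinted cluster of chromosome 14 held 23, 35, 38 and 2 reads. The chromosome 19 cluster held 95, 99, 14 and 7.

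**Figure D2:**
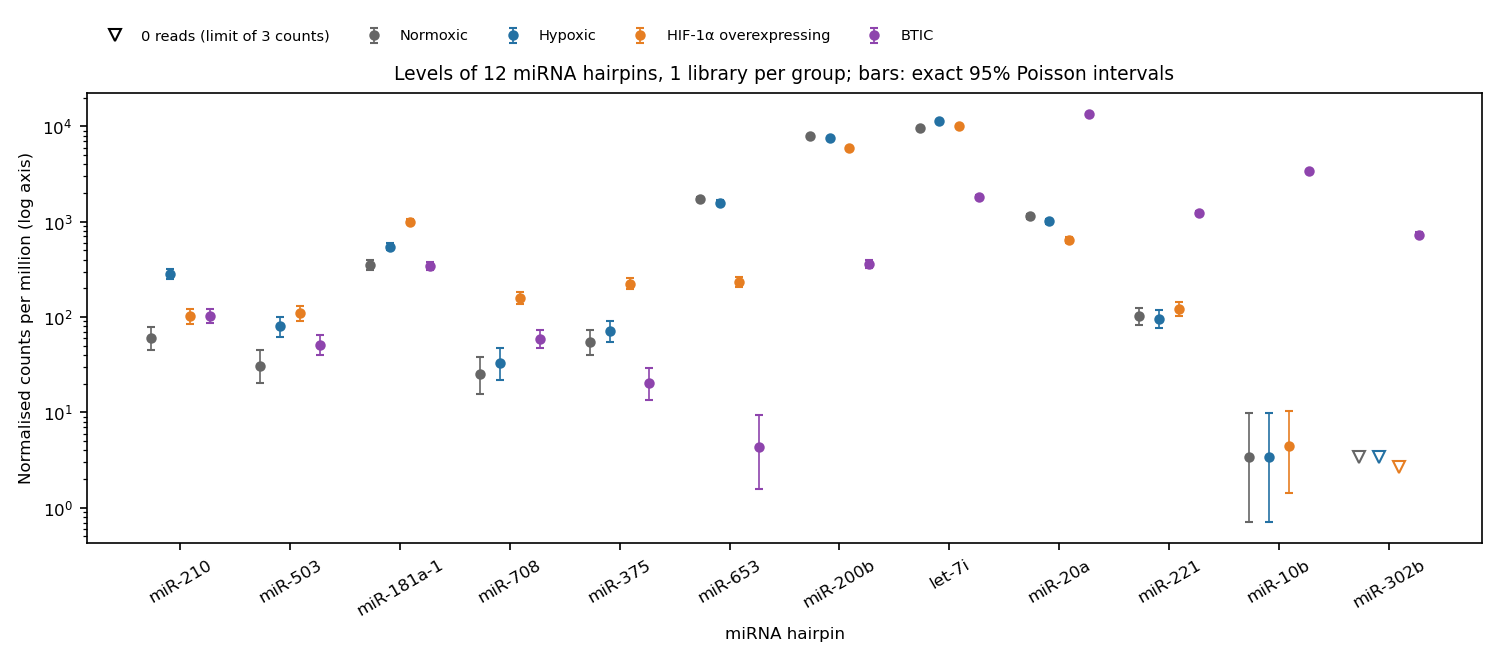
Normalised CPM (y axis, log scale) of 12 miRNA hairpins (x axis) in the 4 libraries, with exact 95% Poisson intervals for counting error. Open triangles stand for 0 reads, drawn at the limit of 3 counts. miR-210 stood at 60.2, 282, 102 and 102 CPM in the normoxic, hypoxic, HIF-1 alpha and BTIC libraries.

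**Figure D3:**
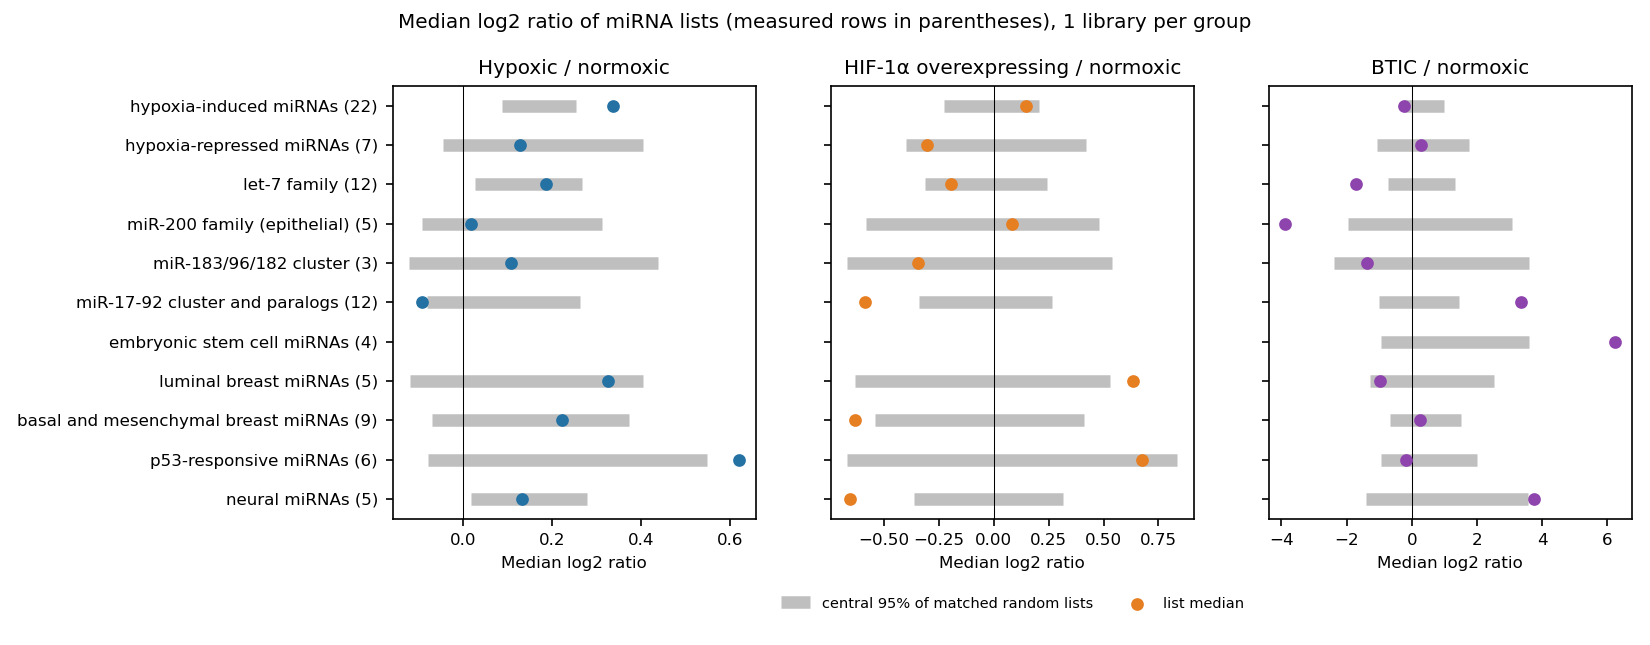
Median log2 ratio to the normoxic library (x axis) of each list with at least 3 compared rows, with the number of rows in parentheses, for the 3 comparisons. Grey bars span the central 95% of 10000 matched random lists under TMM scaling, and rows with 0 reads in 1 library enter at their lower bound. The number of lists outside it was 3 of 10, 4 of 10 and 5 of 11, and the hypoxic medians other than hypoxia-induced, luminal, p53-responsive and miR-17-92 turn below 0 under total scaling. The BTIC number includes the embryonic stem cell list, whose rows met the read minimum through BTIC reads alone. Some lists share members.

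Against the hypoxic library, 16 rows were higher and 23 lower in the HIF-1 alpha library. MIR210 was 2.77-fold lower there (2.22 to 3.49), MIR653 6.79-fold lower (5.96 to 7.78) and MIR708 4.76-fold higher (3.25 to 7.41). Total scaling gave 39 higher and 12 lower. In the BTIC library 70 rows were higher and 62 lower than in the hypoxic library, and MIR210 was 2.76-fold lower (2.24 to 3.42) under TMM but at 1.11-fold (0.897 to 1.37) under total scaling. Total scaling gave 157 higher and 21 lower, with 22 of the rows called under TMM on the other side of 1.

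The 3 comparisons share the normoxic library, so their ratios correlate by chance. The log2 ratios of the hypoxic and HIF-1 alpha comparisons correlated across rows at Pearson's r = 0.37 (Spearman's rho 0.32), where unchanged simulated libraries gave 0.52 with counting error alone and 0.51 with an assumed coefficient of variation of 0.4. Their covariance was 0.15, against 0.042 and 0.42 simulated. There were 4 rows higher in both (MIR503, MIR503HG, MIR450A2 and MIR326), against 0.77 for independent lists and 0.10 and 12.4 simulated. MIR503HG repeats the reads of MIR503. MIR450A2 and MIR326 were not higher in the hypoxic library under total, median-of-ratios or upper quartile scaling. The hypoxic and BTIC ratios correlated at -0.03 (rho -0.12), against 0.54 and 0.51 simulated, with a covariance of -0.03 against 0.042 and 0.42. For this pair 1 row was higher in both, against 2.59 for independent lists and 0.12 and 12.4 simulated. The HIF-1 alpha and BTIC ratios correlated at 0.13 (rho 0.087), against 0.59 and 0.51 simulated, with a covariance of 0.30 against 0.042 and 0.42. There were 11 rows lower in both, against 4.68 for independent lists and 0.05 and 8.74 simulated, and 4 higher in both, against 7.44 for independent lists and 0.14 and 12.3 simulated. Neither simulated setting matched these libraries. Counting error alone varies less than they did. The coefficient of variation of 0.4 gave 12.4 rows higher in both for the pairs with the hypoxic library, where only 8 were higher in that library. The simulated values therefore set no expected level, and an observed value under them has no reading. With 1 normoxic library the control could not be split, and part of each excess may come from it.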

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

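No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. Counting hairpin rows alone and scaling by the total without miR-21 were chosen after seeing the data. The number of rows at least 2-fold higher or lower stayed within 1.5 times of the main count under each scaling, without a read minimum, with copies summed and with a prior count of 5, in all 5 comparisons. That sum hides its parts, since a scaling trades lower rows for higher ones. Under total scaling the higher and lower rows went from 77 and 53 to 163 and 21 for BTIC against normoxic. For HIF-1 alpha against normoxic they went from 23 and 21 to 39 and 14, and for BTIC against hypoxic from 70 and 62 to 157 and 21. With at least 500 reads the number of rows higher or lower was 2 for hypoxic, 14 for HIF-1 alpha and 78 for BTIC against normoxic (8, 44 and 130 in the main analysis). It was 16 and 79 for HIF-1 alpha and BTIC against hypoxic (39 and 132). With the 4-fold threshold it was 2, 13 and 69, and 10 and 76. Fewer rows or a stricter rule bring such drops by construction. The lists outside the central 95% numbered 2 rather than 4 for HIF-1 alpha with copies summed, where the neural list had too few rows. The median of the basal and mesenchymal list in HIF-1 alpha turned from -0.63 to 0.0226 with at least 500 reads, and that of the miR-17-92 list in the hypoxic library from -0.09 to 0.00843 without a read minimum (the cause was not tested). The correlation of hypoxic and BTIC ratios was -0.11, and that of HIF-1 alpha and BTIC ratios 0.0813, with at least 500 reads (the cause was not tested). Of 339 log2 ratios under an alternative of miR-210 and the rows named for their size, 0 changed sign. For miR-210 in HIF-1 alpha and BTIC, short of the 2-fold rule, a change of sign was looked for under the scalings alone. The other rows were chosen for ratios of at least 2-fold, and a read minimum leaves a ratio as it is. The 0 is therefore no measure of stability. Of the rows named as list members or most abundant, 14 of 41 (hypoxic), 9 of 42 (HIF-1 alpha) and 17 of 36 (BTIC) changed sign under a scaling. Of 275 list medians, 7 left the outer 5% and 0 entered it. A scaling moves all rows of a comparison alike and cannot change a list's place among random lists. Only the alternatives that were not scalings could therefore move a list, and the count is no measure of stability under scaling.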

Other observations

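The groups and tests in this part were chosen after the results were seen, except for the chromosome 19 list. The 6 hairpins of the X chromosome cluster of miR-450, miR-542, miR-503 and miR-424 (133674215 to 133680741) had a median log2 ratio to the normoxic library of 1.27 in the HIF-1 alpha library, with 5 of 6 higher (3 under median-of-ratios and 4 under upper quartile scaling). The 4 rows of miR-181a and miR-181b, from chromosomes 1 and 9, summed to 2.96-fold (2.75 to 3.20) of the normoxic library in the HIF-1 alpha library and 1.53-fold (1.41 to 1.67) in the hypoxic library. In the BTIC library all 7 hairpins from MIR532 to MIR502 on the X chromosome (49767754 to 49779291) were higher, with a median of 1.85, and 5 of 7 under upper quartile scaling. MIR301B and MIR130B on chromosome 22 had 1 and 28 normoxic and 48 and 394 BTIC reads. MIR99B, MIRLET7E and MIR125A on chromosome 19 were all lower in BTIC, with a median of -1.29, smaller than the shift of 1.37 that total scaling brings.

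The 3 hairpins of miR-196, which lie within HOX gene clusters, were lower in HIF-1 alpha and higher in BTIC. MIR196A1 and MIR196B had 30 and 22 normoxic reads, 8 and 6 reads in the HIF-1 alpha library and 110 and 300 in the BTIC library. MIR196A2 was 5.45-fold lower in HIF-1 alpha (2.80 to 12.6) and 2.12-fold higher in BTIC (1.52 to 3.07). MIR10A had 93, 78 and 1724 reads in the same libraries. Of the 6 hairpins of HOX clusters compared, 4 were lower in HIF-1 alpha (3 under total scaling) and 5 were higher in BTIC (3 under median-of-ratios and upper quartile scaling). MIR615 was lower in both libraries, and in neither under total scaling. MIR31 had 0 reads in the 3 MCF7 libraries and 51 in BTIC, at least 10.8-fold higher than normoxic, and MIR873 had 58 BTIC reads with 0, 1 and 0 elsewhere. Both met the read minimum through BTIC reads alone, so a higher value there was fixed in advance.

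In the BTIC library 130 of 238 rows differed at least 2-fold from the normoxic library, some of them rows that met the read minimum through BTIC reads alone. The lower total of that library is argued against. Outside miR-21 it held 396036 reads, more than the 193968 of the normoxic library, repeats in host rows included. The hypoxic library, with 8 rows called in full, differed in at most 13 rows when thinned to the BTIC total over 20 thinnings. Because that library was close to the normoxic one, the thinning shows only that a lower total adds few calls. A wrong scaling factor is also argued against, since no single factor between 1/16 and 16 left fewer than 116 rows. A mostly unchanged MCF7 culture with other cells mixed in is limited by MIR653 with MIR489, the MIR200B cluster and MIR335, whose shares of reads allow at most 1.36%, 14.9% and 17.7% of unchanged normoxic MCF7 RNA. These shares are of all reads, repeats in host rows included. Host rows held 18.4% of BTIC and 3.61% of normoxic reads, so over hairpin reads alone the limits would be somewhat higher. A library of other cells than the label names cannot be told apart from a change of state in MCF7 cells, because miR-21, still its most abundant miRNA at 41.4% of reads, is common to many lines and there was 1 library, matched to its sample by reasoning from a column name.

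MIR653 and MIR489, neighbours on chromosome 7, summed to 7.46-fold lower in the HIF-1 alpha library (6.56 to 8.52) and 416-fold lower in the BTIC library (190.7 to 1136), or 161-fold under total scaling and 614-fold under the upper quartile. The chromosome 19 cluster, with far fewer reads, was 8.72-fold lower (4.95 to 16.6) and 21.5-fold lower (10.02 to 54.8), the latter 8.29-fold under total scaling and 31.7-fold under the upper quartile. For the chromosome 19 cluster, a list fixed in advance, counting error alone is argued against. No upper limit of its ratios to normoxic exceeded 0.258 under 4 scalings. MIR653 and MIR489 were picked because they were put as lower, which requires an interval that excludes 1. Their low upper limits therefore carry no weight against counting error. A 2-fold drop that hypoxia also makes within the 18 h of the labels is argued against. The lowest ratio of either part in the hypoxic library was 0.783 (0.729 to 0.841, under total scaling), above the bound of 0.5. MIR653 with MIR489 was slightly lower there, at 0.929 (0.865 to 0.998) under TMM. A smaller or slower response to hypoxia was not tested. A difference between lines as kept in culture, such as loss or silencing at these places in a derived line, cannot be told apart from an effect of HIF-1 alpha or of sorting, with 1 library per line.

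The X chromosome miR-450 to miR-424 cluster summed to 1.47-fold (1.23 to 1.75) of the normoxic library in the hypoxic and 2.47-fold (2.12 to 2.88) in the HIF-1 alpha library. The HIF-1 alpha library also lay above the hypoxic library, at 1.68 (1.47 to 1.92) under TMM and 2.30 (2.01 to 2.62) under total scaling, a difference that a low normoxic library does not make. A low normoxic library alone cannot be told apart for either, since ratios to BTIC depend on the scaling and single libraries differed beyond counting error in general. HIF-1 alpha over BTIC was 2.76 (2.41 to 3.16) under TMM and 1.22 (1.07 to 1.40) under total scaling and hypoxic over BTIC was 1.64 (1.40 to 1.92) and 0.533 (0.456 to 0.624), against a bound of 1.5 for each. That low oxygen and HIF-1 alpha may both raise this cluster is a hypothesis that these libraries do not test.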
